A study of Mus musculus with 4 samples.

How the data were processed

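Liver RNA of 4 female BALB/c mice was measured on 4 whole-genome oligonucleotide arrays of Agilent with 1 dye, Cy3. The labels name 2 control mice and 2 LB1 mice, with replicate numbers 1 and 2 in each group. Each sample is named as a separate mouse, so the spread between arrays of a group holds both animal and technical variation.

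The deposited scanner files hold, per the file headers, spot intensity on a linear scale from Feature Extraction 10.5.1.1 and scanner G2505C. The design text names another version of both. Per the file headers, the processed signal had its background removed and was detrended within each array, and nothing was done between arrays. The deposited table of the whole series holds the mean spot intensity rounded to a whole number, on a linear scale, without background correction, centring or scaling between arrays: each value lay within 0.5 of the mean signal of the same spot and array in 100% of spots. Its column medians were 70.0 and 65.0 for the control arrays and 62.0 and 45.0 for the LB1 arrays. The submitters' own comparison used GeneSpring's default scaling and Student's test at an unadjusted threshold with a minimum of 2-fold, per the labels of the series.

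Control spots and spots marked as outliers by the scanner software were left out. The log2 of the processed signal was taken, the 75th percentile of each array's 43379 non-control spots was subtracted, and spots of a probe were averaged, which gave 41174 probes. A probe was tested if it was well above background on both arrays of at least 1 group (22974 probes). Probes were named through their accessions with the RefSeq table of assembly GRCm38.p6 (24844 probes), through the file's current symbol (6045) or a unique older symbol (1810). The file's name was kept for 8475. Probe coordinates are those of the files, on mm9, counted from 1.

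LB1 and control arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all tested probes. A call is an adjusted p under 0.05. Positive log2 differences are LB1 minus control. A gene was represented by its brightest probe over the 4 arrays. A probe that is not well above background on either array of a group has only a bound there: its fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. A probe saturated on both arrays of a group has a value there that is a lower limit. In that case an LB1 minus control difference above 0 is only an upper limit.

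Gene lists for pathways and cell types (35 in all, 799 distinct tested genes, 47 of them in more than 1 list) were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera compares a list with all other genes, so a shift shared by all genes does not enter it. List medians are given relative to the median of all 15784 tested genes. The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 3 PCR targets of the study, the 10 genes per direction with the largest called difference whose LB1 arrays both lay on one side of both control arrays, the 4 members with the smallest p of each list past the test, and 1 or 2 members or the count alone for the others. Genes known only by an accession, clone or provisional name were counted and not named. The 3 PCR targets were probably chosen on these arrays and are no independent evidence. Their exact permutation test has 6 assignments.

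The fit was tested on simulated data with the LB1 against control layout over 22958 probes. At a simulated 2-fold change 0 of 50 probes were recovered, at 4-fold 10, at 8-fold 37 and at 16-fold 46, with 10 false calls. None of 29 unshifted lists was called. The simulated noise was independent between probes and had the same spread in both groups. The simulation therefore cannot show how often lists of correlated genes, or groups of unequal spread, give false calls. With few changed probes, as there, the adjusted threshold is stricter than with the many changed probes of the real arrays.

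Each slide held 1 control and 1 LB1 array of the same replicate number and was scanned separately, so the replicate number, the slide and the scan are the same block. The labels do not say that a number marks a shared batch, and slide and scan come from the file headers. Deviations from the group means of the same-numbered arrays correlated at 0.151 across probes, which are not independent replicates. Values with this block and within each slide are given beside the main ones.

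Alternatives were normexp background correction with an offset of 50, quantile normalization, the array median in place of the 75th percentile, no filter and a filter on all 4 arrays, eBayes with a trend and robust settings, array weights, the methods' t-test, the rounded series table, the block, 1 probe per gene, other list tests and each array left out. Removal of saturated probes and cyclic loess were added after seeing the data. No array was left out of the main comparison. The number of arrays limits the precision of every value.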

Results

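The series asks how a Lactobacillus isolate from ostrich affects body weight, gut bacteria and metabolism in mice. The arrays address its metabolic part in the liver, 20 days after inoculation. Livers of 2 mice of the group labelled LB1 and of 2 control mice were each measured on 1 array. The labels do not say what LB1 stands for or what the control mice received.

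The arrays of the 2 groups differed in brightness. The 75th percentile of the processed signal was 410.9 and 414.7 on the control arrays against 146.9 and 80.8 on the LB1 arrays (replicates 1 and 2). Spots well above background numbered 25861 and 24736 against 22921 and 20311, and saturated spots 266 and 297 against 104 and 64. RNA spike-ins, which are added in fixed amounts at labelling, were not dimmer on the LB1 arrays: the median of the 6 spike-ins within range was 1.37-fold higher there. Relative to them the median tested probe was 4.66-fold lower on the LB1 arrays. All values below are scaled within each array and carry no information on the total amount of RNA. Across tested probes, the 2 control arrays correlated at 0.989 and the 2 LB1 arrays at 0.973. Pairs of a control and an LB1 array correlated at 0.906 to 0.95.

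LB1 livers differed from control livers at 7439 of 22974 probes, 4409 higher and 3030 lower, by limma with Benjamini-Hochberg adjustment. Of these, 3748 and 2549 differed at least 2-fold. With 1 probe per gene, 2662 named genes were higher and 1355 lower of 13003. The largest rises in the main setting were at Cdcp1, Nkain4, Gpc3 and Msln and the largest falls at Ugt1a9, Cyp4a31, Adgrl4 and Cd1d2. Several of these rest on signals not well above background, and the order changed with the background correction, as given below. The share of calls in each direction depended on the scaling. It was 59.3% higher in the main setting (median of all probes 0.16), 44.9% with quantile normalization (3138 higher, 3845 lower, median 0.01) and 18.9% with the array median as reference (1658 higher, 7126 lower, median -0.47). With background correction by normexp it was 71%, it reached 74% on the rounded series values (10691 higher, 3755 lower), and with cyclic loess 46.1%. Of the 7439 probes, 6041 were also called in the same direction after quantile normalization and 4568 with the array median as reference. With slide as a block, 4190 probes were higher and 2769 lower. Over all tested probes, 84.4% had the same sign within both slides. Without control replicate 1 the count was 139 and without control replicate 2 it was 1, where the remaining spread comes from the LB1 pair alone and the lone control is assumed to vary alike. The standard deviation of the difference between 2 arrays of a group was 0.71 for LB1 and 0.45 for control. Without LB1 replicate 1 it was 11027 and without LB1 replicate 2 6017. Of 907 genes with at least 2 called probes, 240 had probes called in opposite directions (26.5%). With the signs shuffled among these probes, 483 were so on average.

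The genes with the largest rises are given here with their values. Msln, the mesothelial surface protein mesothelin (chromosome 17, 25885569 to 25885628), went from a control mean of -2.53 ± 2.32 to 3.51 ± 1.22 (SD, n = 2 each, log2 relative to the array's 75th percentile). Its log2 difference was 6.04 (SE 1.19, adjusted p = 0.0267), with 3.54 on slide 1 and 8.54 on slide 2. Rspo1, a secreted activator of Wnt signalling, rose by 5.93 (SE 1.26, adjusted p = 0.0297), and Gpc3, a cell surface proteoglycan of fetal liver, by 6.04 (SE 0.76, adjusted p = 0.0211). Cdcp1, a transmembrane protein of epithelia, rose by 6.27 (adjusted p = 0.0212) and Nkain4 by 6.09 (adjusted p = 0.0243), with its other probe at 2.02. Myl7, the atrial myosin light chain, rose by 5.65, Trim55, a sarcomere-associated ubiquitin ligase, by 5.62, Ddx25, a testis RNA helicase, by 5.88 and Cybrd1, an iron reductase, by 5.40. The probe of Usp29, a ubiquitin peptidase gene, was not well above background on the control arrays and was at least 21.6-fold higher on the LB1 arrays (adjusted p = 0.022). This bound holds for the main background correction and scaling only. Rspo1, Gpc3, Cdcp1, Nkain4 and Cybrd1 were well above background on only 1 of the 2 control arrays. The size of these rises depended on the background correction. Over the 10 genes they were 2.47 to 4.75 with normexp and 2.73 to 5.15 on the series values, all past the test. With normexp Cdcp1 rose by 3.52, Nkain4 by 3.60, Gpc3 by 3.13, Msln by 4.56, Rspo1 by 3.74, Ddx25 by 4.75, Myl7 by 3.69, Trim55 by 4.11, Usp29 by 2.52 and Cybrd1 by 2.47. Over these 10 genes in the main setting the difference was 3.26 to 4.48 on slide 1 and 7.14 to 8.56 on slide 2, and adjusted p with the slide block was 0.0308 to 0.036. The slide 2 values of Rspo1, Gpc3, Cdcp1, Nkain4 and Cybrd1 rest on control signals not well above background and are not exact. The same holds for Usp29 on both slides. In a marker list of mesothelium, the cell layer that covers the liver, 15 of 17 tested genes were higher past the test and none lower. That list of 21 genes was written after the data were seen and includes Msln, Rspo1, Nkain4 and Myl7. Of the 13 tested markers outside the genes named here, 11 were higher past the test. Markers dim on the control arrays enter the test only through the LB1 arrays.

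The genes with the largest falls had varied functions. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6193456 to 6193515), went from 5.24 ± 0.65 to 2.29 ± 0.14 (SD, n = 2 each), a log2 difference of -2.95 (SE 0.36, adjusted p = 0.0211). Its second probe was at -1.62 and did not pass (adjusted p = 0.0772). Rtn4, an endoplasmic reticulum protein, differed by -3.26 (SE 0.27, adjusted p = 0.0201) and -3.36 at its 2 probes. Cyp4a31, a fatty acid hydroxylase, differed by -3.83 (SE 0.63, adjusted p = 0.0229) and was well above background on 1 of the 2 LB1 arrays. Cd1d2, a lipid antigen-presenting molecule, differed by -3.27 (SE 0.72). Pon2, a lactonase, differed by -3.20 (SE 0.33), with its other probes at -3.54 and 0.02. The remaining 5 were not well above background on either LB1 array. The probe of Ugt1a9, a UDP-glucuronosyltransferase (chromosome 1, 89968031 to 89968090), was at least 14.7-fold lower (adjusted p = 0.0201). That of Rad1, a DNA damage checkpoint gene, was at least 6.14-fold lower, that of Adgrl4, an endothelial adhesion receptor, at least 5.96-fold, that of Fut8, a fucosyltransferase, at least 3.58-fold and that of Adcy2, an adenylate cyclase, at least 2.66-fold. These bounds hold for the main background correction and scaling only. The size of most falls also depended on the background correction. With normexp Ugt1a9 was at -1.49 and Rad1 at -0.56, Adgrl4 at -0.21 (adjusted p = 0.151) and Fut8 at -0.05 (adjusted p = 0.811) no longer passed, and Adcy2 turned to 0.33. Cyp4a31 was then at -0.95, Pon2 at -1.45 and Cd1d2 at -1.94, while Rtn4 at -3.07 and Cyp7a1 at -3.38 moved less. On the series values Fut8 (-0.35, adjusted p = 0.159) and Adcy2 (-0.03) did not pass. Over these 10 genes in the main setting the difference was -5.30 to -1.67 on slide 1 and -4.82 to -2.88 on slide 2, and adjusted p with the slide block was 0.0308 to 0.0358. The slide values of Ugt1a9, Rad1, Adgrl4, Fut8 and Adcy2 rest on LB1 signals not well above background and are not exact. The same holds for Cyp4a31 on slide 2. Of all 20 genes, no call was kept without control replicate 2, and 7 were lost without control replicate 1 and 6 without LB1 replicate 2.

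**Figure D1:**
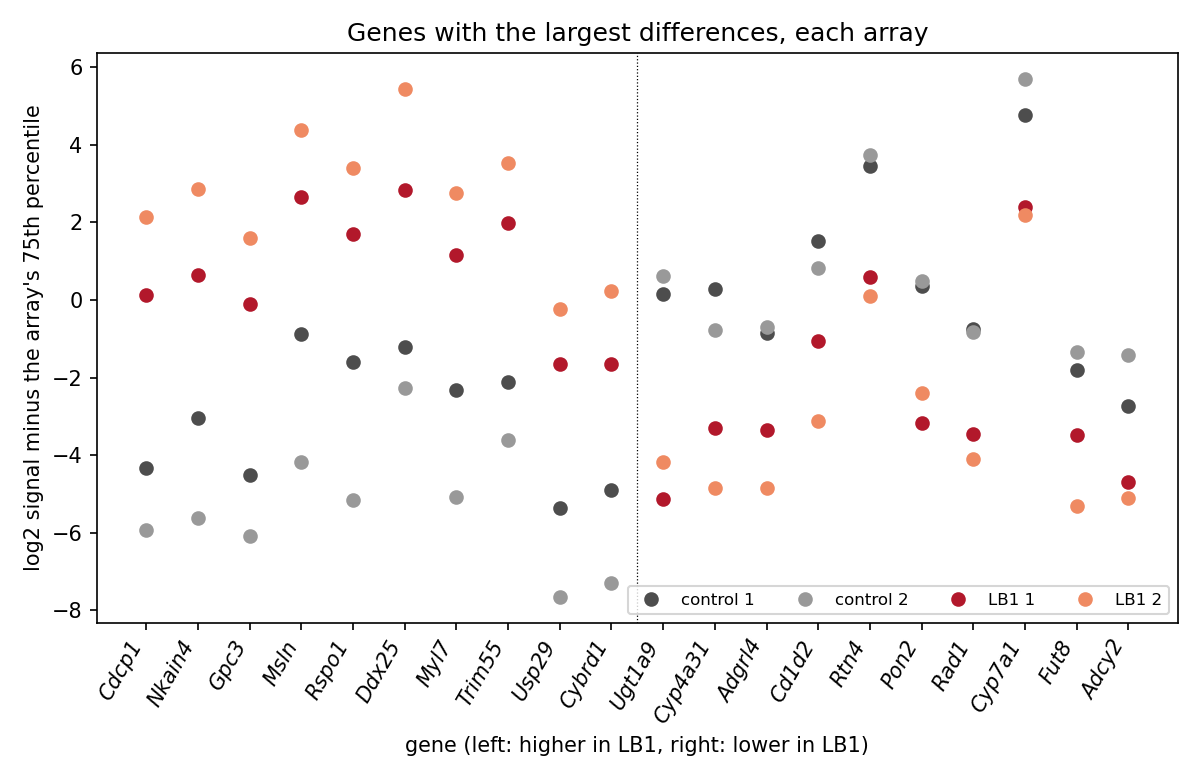
Log2 signal minus the array's 75th percentile (y axis) of the 20 genes with the largest called differences (x axis), 1 point per array, for control replicates 1 and 2 and LB1 replicates 1 and 2. For the 10 genes on the left both LB1 points lie above both control points, and for the 10 on the right they lie below. The slide differences on the left reach 8.56, at Rspo1, whose control replicate 2 was not well above background.

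The study's own PCR targets were compared to see how these genes, named in the design text, read on the arrays. Gapdh, a glycolytic enzyme used as housekeeping gene (chromosome 6, 125112515 to 125112573), was at 6.39 ± 0.27 in control and 6.36 ± 0.08 in LB1 livers (SD, n = 2 each). The difference was -0.04 (SE 0.24, adjusted p = 0.919), against a median of 0.30 over all genes. It was -0.47 with quantile normalization and -0.67 with the array median and with cyclic loess, none past the test. With normexp it was -0.62 and past the test (adjusted p = 0.0216). Cyp2e1, the ethanol-oxidizing cytochrome P450 (chromosome 7, 147959585 to 147959644), was saturated on both control arrays and on neither LB1 array. Its measured difference of 1.01 (SE 0.29, adjusted p = 0.0524) is therefore only an upper limit, and its direction is undetermined. Pdpk1, the kinase that activates Akt in insulin signalling, had 3 probes that disagreed. The brightest (chromosome 17, 24216513 to 24216572) was at -0.48 (SE 0.22, adjusted p = 0.142) and another at -0.47 (SE 0.23, adjusted p = 0.173). The latter turned to 0.43 with normexp, past the test as higher (adjusted p = 0.0168), and to 0.18 with the series table. With the array median as reference the brightest and this probe were at -1.12 and -1.10 and past the test. The third probe (chromosome 17, 24243816 to 24243875) rose by 4.04 (SE 0.67, adjusted p = 0.023; 0.0308 with the slide block), 2.84 on slide 1 and 5.24 on slide 2. Without either control array this call was lost, at 4.26 and 3.82. The exact permutation test, 2-sided, gave p = 0.333 for Cyp2e1 and each Pdpk1 probe and p = 1 for Gapdh, and 0.333 is the smallest p that 2 arrays against 2 allow.

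Genes of drug and toxin handling were called lower more often than higher on the LB1 arrays, which were also dimmer and carried higher mesothelial markers, as given above. Of 44 tested genes of phase II conjugation and transport, which attach polar groups to foreign compounds and export them, 11 fell, 27 did not pass and 6 were higher, 5 of those 6 with probes saturated on at least 1 array (7 higher and 13 lower adjusted over the list alone). The list median lay 0.64 below that of all genes on the log2 scale (-0.52 on slide 1, -0.76 on slide 2), with camera's adjusted p = 0.0255, or 0.736 with an estimated correlation. Ugt1a9 was named above. Ugt1a1, which conjugates bilirubin, differed by -2.71 (SE 0.23), Ugt2b34 by -1.92 (SE 0.24) and Abcg2, an efflux transporter, by -1.66 (SE 0.21). Of 44 genes of cytochrome P450 and phase I metabolism, 12 fell, 26 did not pass and 6 were higher, all 6 with saturated probes (7 higher and 14 lower adjusted over the list alone). The list median differed by -0.53 from all genes (-0.43 and -0.71 on the slides), with camera's adjusted p = 0.029, or 0.736 with an estimated correlation. Cyp2c54 differed by -2.60 (SE 0.32), Cyp2b10, a target of the xenobiotic receptor CAR, by -1.82 (SE 0.22) and Cyp3a25 by -1.53 (SE 0.21). Adh1, the main alcohol dehydrogenase, was saturated on both control arrays, so its 1.51 is an upper limit, and its other probe was at -0.31. With quantile normalization no phase I gene was higher and 21 were lower, and 1 phase II gene was higher and 15 were lower. Without LB1 replicate 1 both missed the threshold, at adjusted p = 0.0606.

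Enzymes of nitrogen disposal were compared in the same way. Of 35 tested genes of the urea cycle and amino acid catabolism, 7 fell, 1 rose and 27 did not pass (the same counts adjusted over the list alone), with a list median of -0.56 against all genes (-0.27 and -0.79 on the slides) and camera's adjusted p = 0.029. It was 0.736 with an estimated correlation and 0.0509 without LB1 replicate 2. Cps1, which commits ammonia to the urea cycle, differed by -1.24 (SE 0.24), Hgd, of tyrosine breakdown, by -1.82 (SE 0.29) and Kmo, of tryptophan breakdown, by -1.42 (SE 0.27). Uroc1, of histidine breakdown, was higher by 1.12 (SE 0.22), but did not pass with quantile normalization (0.71, adjusted p = 0.0511). With quantile normalization 0 genes of this list were higher and 13 lower.

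Among genes with a higher level in female than male liver, 6 of 20 fell and 2, both with saturated probes, were higher (the same counts adjusted over the list alone). The list median was -0.81 against all genes (-0.54 and -1.09 on the slides), with camera's adjusted p = 0.0255. It was 0.736 with an estimated correlation and 0.0606 without LB1 replicate 1. Of its genes, 9 are also in the phase I list. Rtn4 was named above. Acot3, a peroxisomal thioesterase, differed by -2.48 (SE 0.28) and Cyp2b10 by -1.82, while Cyp3a41a was saturated on both control arrays with an upper limit of 1.35. Of 16 male-biased genes, 4 were higher, 2 of them without saturation, and 3 lower, with Ugt2b38 at -2.65 and Cyp4a12b at -2.02 (camera's adjusted p = 0.79). Against all genes that list's median was 0.79, or -0.08 with quantile normalization.

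Cytosolic ribosomal proteins were the list past the test in the other direction, and that result rests on the scaling and on saturated probes. Of 47 genes, 20 were higher and 2 lower (23 and 4 adjusted over the list alone), but 14 had saturated probes and only 6 of the 20 higher ones did not. The median was 0.50 above all genes (0.29 and 0.66 on the slides), with camera's adjusted p = 0.029, or 0.736 with an estimated correlation. With quantile normalization 3 were higher and 6 lower and the median was 0.01 above all genes (adjusted p = 0.987), and without saturated probes the adjusted p was 0.422. It was 0.0769 without control replicate 1 and 0.0668 with the mean over all probes of a gene. Rpl4 differed by -1.39 (SE 0.21), whereas Rpl27, Rps29 and Rplp0 were saturated on both control arrays, with upper limits of 1.75, 1.50 and 1.80. Of 47 oxidative phosphorylation genes 19 were higher and 7 lower, 14 of the higher ones without saturation, against 4 and 8 with quantile normalization (camera's adjusted p = 0.199). Sdha was at -2.00 (SE 0.35).

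Other metabolic lists held called genes in both directions and did not pass as lists in the main setting. With an estimated correlation adjusted p was 0.736 or more for each of them. In bile acid synthesis and transport, 5 of 23 genes fell and 4 rose (camera's adjusted p = 0.33, or 0.022 with quantile normalization). They included Slc10a1, the bile acid importer of hepatocytes, at -2.45 (SE 0.21) and Cyp27a1, of the alternative synthesis route, at -2.15 (SE 0.21). In fatty acid oxidation and PPAR alpha targets 12 of 39 were higher, 7 of them without saturation, and 6 lower (adjusted p = 0.372, or 0.022 lower with quantile normalization). In apolipoproteins and lipoprotein handling 9 of 25 were higher, 1 of them without saturation, and 6 lower (adjusted p = 0.429, or 0.0267 lower with quantile normalization), with Lipc, hepatic lipase, at -1.89 (SE 0.25). In the acute phase response 8 of 31 were higher, 1 of them without saturation, and 5 lower (adjusted p = 0.651, or 0.0267 lower with quantile normalization), with Serpina3n at -2.27 (SE 0.25). In cholesterol synthesis 6 of 25 were higher, 5 of them without saturation, and 2 lower (adjusted p = 0.9), with Srebf2, its main transcription factor, at 1.76 (SE 0.27). In fatty acid synthesis 4 of 30 were higher, 3 of them without saturation, and 2 lower (adjusted p = 0.79), with Fads1 at -1.76. In glycolysis, gluconeogenesis and glycogen 9 of 29 were higher, 7 of them without saturation, and 5 lower (adjusted p = 0.709), with Eno1 at -1.97. Background correction and filter moved these lists. With normexp and on the series values most called probes were higher on the LB1 arrays, as given above. Without the filter, which lets in dim probes, 17556 were higher and 3127 lower, against 4409 and 3030 in the main setting. The differences with normexp, the series values and no filter were not broken down by signal decile. Camera compares a list with all other genes, so these settings cannot tell a fall of a list from a rise of the other genes. With normexp all 7 were lower past the test: bile acid 0.00299, fatty acid oxidation 0.00317, glycolysis 0.00856, apolipoproteins 0.0114, cholesterol synthesis 0.0218, acute phase 0.0274 and fatty acid synthesis 0.0287. Without the filter on dim probes 6 of the 7 passed as lower (glycolysis 0.00821), all but cholesterol synthesis. On the series values 4 did, those of bile acid, fatty acid oxidation, apolipoproteins and glycolysis (0.0318). Some lists also passed as lower with the main background correction and filter kept. Without saturated probes these were apolipoproteins (0.00543) and fatty acid oxidation (0.032). With cyclic loess they were bile acid and fatty acid oxidation (0.0236 each). The others of the 7 did not pass in either setting.

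Signalling and stress lists did not pass as lists in the main setting. In insulin and PI3K signalling 1 of 28 genes was higher and 2 lower (adjusted p = 0.301), Sgk1 at -1.46 and Insr, the insulin receptor, at -1.39 with its other probe of opposite sign. Of 22 immediate early genes 7 rose and none fell (adjusted p = 0.0643, 0.045 with the slide block and 0.0267 with quantile normalization, but 0.736 with an estimated correlation and 0.903 without the filter on dim probes), with Btg2 at 1.57 and Klf4 at 1.44. Of 19 clock genes 2 were higher, 1 of them without saturation, and 2 lower (adjusted p = 0.0693, 0.045 with the slide block and 0.000108 without the filter on dim probes, but 0.736 with an estimated correlation and 0.0595 with quantile normalization), with Noct at -2.27 and Nr1d2 at -1.46. Of 37 interferon response genes 4 were higher and 5 lower (adjusted p = 0.79), of 30 cell cycle genes 1 and 2 (0.301), of 32 heat shock and unfolded protein genes 2 and 3 (0.9) and of 21 NRF2 targets 5 and 1 (0.199). Only 2 of the 5 higher NRF2 targets were without saturation, and with quantile normalization 0 were higher and 2 lower. For heat shock the list median lay above and the mean below that of all genes, and for cholesterol synthesis both lay below while camera's direction was upward. Insulin and PI3K signalling passed as lower with normexp (0.00874), without the filter on dim probes (0.000818) and on the series values (0.0231), and the clock list with normexp (0.0209) and the series values (0.0176). Heat shock turned to lower past the test with normexp (0.0275) and without the filter (0.0385). Without the filter the interferon (0.00476) and cell cycle lists (0.000268) also passed as lower. With an estimated correlation camera's adjusted p was 0.736 for the insulin and cell cycle lists, 0.899 for interferon and 0.923 for heat shock. The limit given for the metabolic lists with normexp, the series values and no filter holds here too.

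Markers of the cell types a liver sample can hold were compared in the same way. Of 18 hepatocyte identity genes 10 were higher and 2 lower, but 13 had saturated probes and only 1 of the higher ones did not, so their direction is undetermined (camera's adjusted p = 0.222). Among pericentral genes 3 of 19 were higher and 3 lower (0.199), and among periportal genes 3 of 19 were higher and 4 lower (0.301), with 1 higher gene without saturation in each. With quantile normalization these lists were lower, with adjusted p = 0.0267 and 0.0292, and with an estimated correlation both had 0.736. B and plasma cell markers rose at 5 of 13 genes and fell at none (0.122), with Cd79a at 1.71 (SE 0.21), and T and NK cell markers rose at 5 of 18 and fell at none (0.448), with Thy1 at 1.74. Of Kupffer cell and macrophage markers 1 of 21 was higher and 2 were lower (0.271), with Vsig4 at -1.59, and of neutrophil markers 2 of 7 were higher (0.46). Erythroid markers were higher at 5 of 10 genes, 3 of them without saturation, and lower at 1 (0.301), with Alas2, of haem synthesis, at 2.44 (SE 0.25). Endothelial markers were higher at 3 of 22 and lower at 3 (0.199), with F8 at -2.11. Stellate cell and fibroblast markers rose at 6 of 21 and fell at none (0.526), with Pdgfrb at 1.25. Cholangiocyte markers were higher at 4 of 10 and lower at 1 (0.534), with Krt7 at 4.69 and Spp1 at -1.53. With normexp and on the series values, B and plasma cells (0.0274 and 0.04) and T and NK cells (0.00705 and 0.0136) passed as higher. T and NK cells turned to lower without the filter on dim probes and without LB1 replicate 1, not past the test. Kupffer cells (0.0114 and 0.0231) and endothelial cells (0.0444 and 0.0358) passed as lower in these settings, and without the filter at 0.00143 and 0.000268. Pericentral (0.00317) and periportal genes (0.00326) also passed as lower with normexp. With an estimated correlation camera's adjusted p was 0.736 for each list that passed in these settings. The limit given for the metabolic lists with normexp, the series values and no filter holds here too.

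Tissues next to the liver were covered by 3 lists. Skeletal muscle markers rose at 6 of 11 tested genes and fell at none, with a median 1.26 above all genes (camera's adjusted p = 0.0524, 0.0256 with the slide block and 0.022 with quantile normalization). It was 0.736 with an estimated correlation and 0.0605 without the filter on dim probes. The probe of Acta1, skeletal actin, was not well above background on the control arrays. It was at least 6.86-fold higher on the LB1 arrays, in the main background correction and scaling only. Tnnc2 rose by 1.95 (SE 0.22). Exocrine pancreas markers were higher at 5 of 9 and lower at 1 (0.448), with Ctrl at 2.02 and Amy2a5 at -2.48. Adipose markers were higher at 3 of 7, 1 of them with a saturated probe (0.301), and Adipoq was at 0.16 (SE 0.76).

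**Figure D2:**
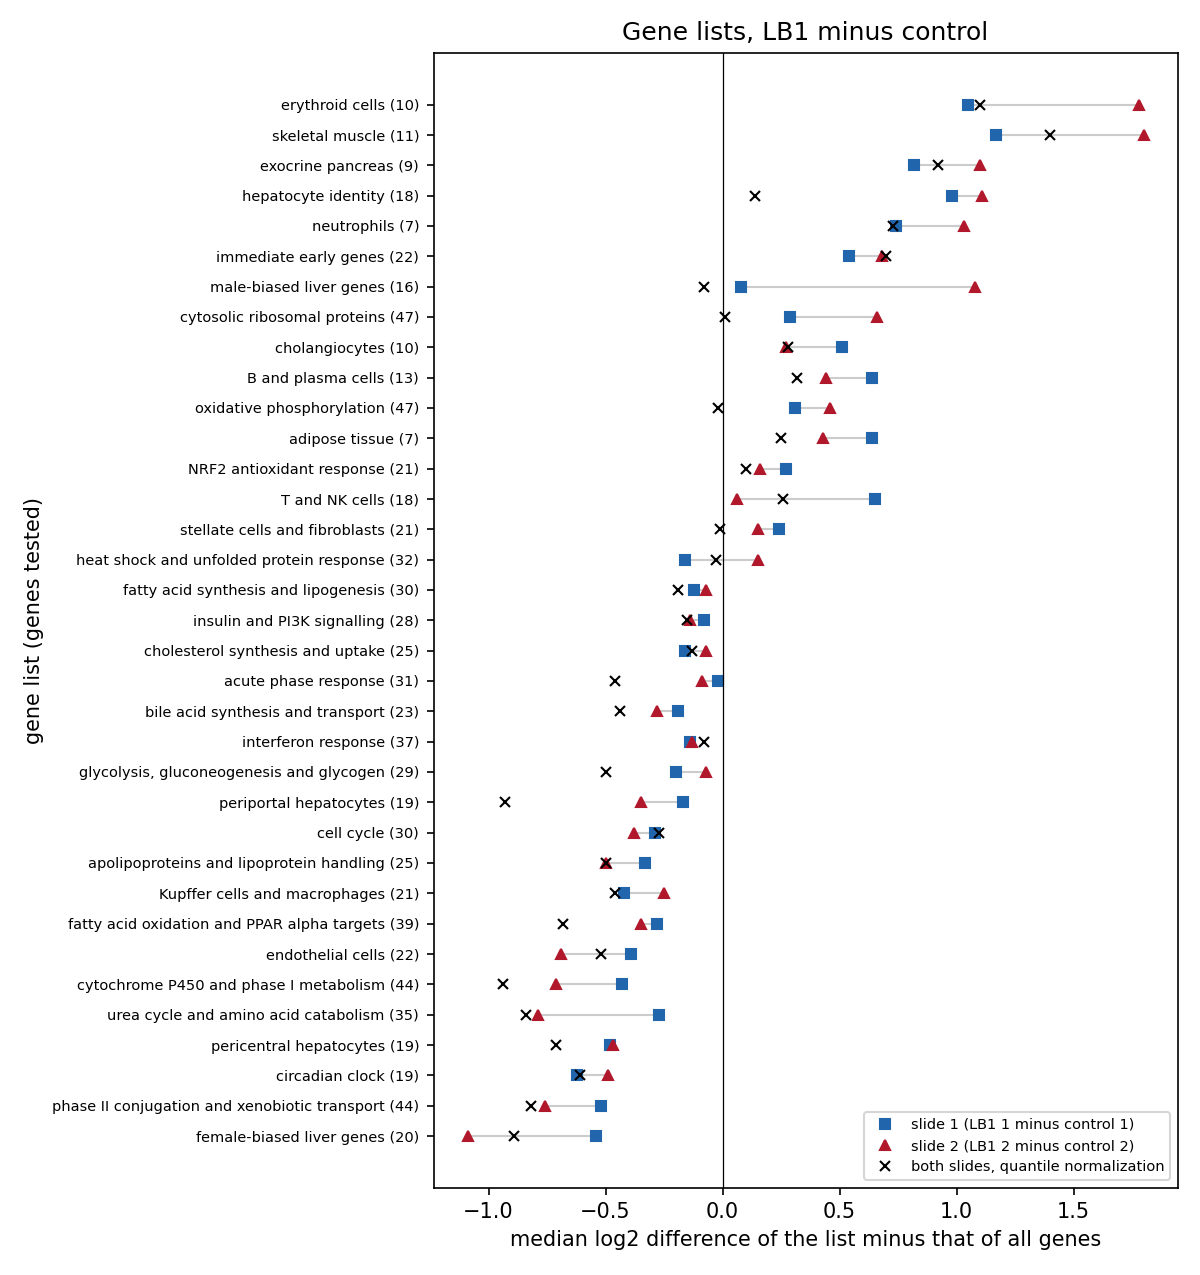
Median log2 difference (LB1 minus control) of each gene list minus that of all genes (x axis), for 35 lists with the number of tested genes in brackets (y axis). Squares and triangles are the 2 slides and crosses the quantile-normalized values of both. Female-biased genes lie lowest on slide 2, at -1.09, and ribosomal proteins move from 0.29 and 0.66 to 0.01 after quantile normalization.

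The rule stated for the study, the methods' t-test at an unadjusted threshold with at least 2-fold, was applied to see what it selects on these values. It selected 2229 higher and 1884 lower probes, 4113 in all, and all 4113 were also called by limma. After Benjamini-Hochberg the methods' t-test called 0 probes, with a smallest adjusted p of 0.0586 and 7016 probes at an unadjusted p under 0.05, against 7439 by limma, which borrows the spread across probes. Limma without adjustment and the same fold gave 7303. With quantile normalization the rule selected 1510 higher and 2431 lower, so the direction held by most of its probes changed with the scaling. As a paired test by slide it selected 1406.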

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

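The removal of saturated probes and cyclic loess were chosen after seeing the data; the other alternatives were not. Where no cause is named, the cause was not tested. The count of 7439 called probes stayed within 1.5 times under 11 of 17 alternatives. It was 15996 with normexp, 14446 with the series table, 20683 without a filter (of 41174 probes tested), 0 by the methods' t-test with adjustment, and 1 to 11027 with 1 array left out, where a group of 1 lends no spread. The replicate block, which is also the slide block, gave 6959 probes, 6313 of them among the 7439. The methods' rule (4113) selected 7787 with normexp, 14198 without a filter, 7303 with limma, 1406 in pairs and 840 to 3407 with 1 array left out. Called lists (5) numbered 0 with an estimated correlation (smallest unadjusted p 0.112), 21 with normexp, 12 with quantile normalization, 19 without a filter, 17 with the series table, 8 with the replicate block, 10 without saturated probes, 10 with cyclic loess and 2 to 7 with 1 array left out. Fry, which asks whether a list moves one way without comparing it with other genes, called 7, none of the 5. The phase I, phase II, urea cycle and female-biased lists kept their direction throughout. Ribosomal proteins turned downward without passing with normexp (adjusted p = 0.226), quantile normalization (0.987) and cyclic loess (0.754).

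Gapdh was at -0.62 and past the test with normexp, and ranged from -0.23 to 0.15 with 1 array left out (0.02 without LB1 replicate 1). Cyp2e1 (1.01, saturated in the controls) passed with the filter on all 4 arrays, with a trend and robust settings and with array weights, each at 1.01, and with the series table at 0.67, and ranged from 0.69 to 1.33 with 1 array left out, where it passed without LB1 replicate 2 (1.33, adjusted p = 0.0341). The brightest Pdpk1 probe passed with normexp (-0.74), the array median (-1.12) and the series table (-0.63). Another passed with the array median (-1.10). It turned to 0.43 with normexp, past the test as higher (adjusted p = 0.0168), and to 0.18 with the series table. The third ranged from 3.06 to 5.02 with 1 array left out. Of the 20 named genes, Adcy2 alone turned, to 0.33 with normexp, and 38 other checks of them lost the call with the direction kept, 33 of those with an array left out. Other splits of the 4 arrays were few, and 3 splits are too few to give a share under 0.05. Limma called 0 probes between the slides (231 at an unadjusted p under 0.05) and 0 for the crossed split (28), against 7439 (11191). Both other splits put an LB1 and a control array in each group, so the difference between LB1 and control adds to their spread. Few calls follow from that, and these splits are no negative control. Signal over background limits the dim genes, and saturation on the control arrays limits 213 bright probes, 140 of which were not saturated on either LB1 array.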

Other observations

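The tests below were chosen after their results had been seen, except that of the escape genes, whose bounds were written beforehand. Mesothelium, the cell layer that covers the liver and lines the abdominal cavity, was not among the lists fixed in advance. A marker list written later names 21 genes, 17 of them tested. Markers dim on the control arrays enter the test only through the LB1 arrays. Of the 17, 15 were higher on the LB1 arrays past the test and none lower. Besides Msln, Rspo1, Nkain4 and Myl7, these were Muc16, the antigen CA125 (log2 difference 5.30, SE 0.91), Igfbp6 (5.01, SE 1.06), the keratins Krt7 (4.69) and Krt19 (4.26), Igfbp5 (4.39), Cldn15 (4.14), Gpm6a (3.28), Slpi (2.25), Aldh1a2 (2.01) and Efemp1 (1.74). The probe of Lrrn4 was at least 8.13-fold higher, in the main background correction and scaling only. Upk3b, at 4.71 (SE 1.39), just missed the test (adjusted p = 0.0556), and Prg4 was at -0.53 (SE 0.30). On control replicate 2 Muc16 (signal 4.72), Igfbp6 (7.78), Krt19 (8.6), Cldn15 (6.27) and Upk3b (2.32) lay below 9.80. That was the lowest signal well above background on that array, so these differences are not exact. Krt7 and Krt19 are also in the cholangiocyte list. The levels were not uniform within a group. The median marker lay 1.99 higher on control replicate 1 than on control replicate 2, and Msln had a processed signal of 222 and 23 on the control arrays against 922 and 1670 on the LB1 arrays.

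A candidate explanation is a larger amount of mesothelial cells in the pieces of LB1 liver. The 13 markers that are not among the genes named for their size had a median of 4.23. That lay above 100% of 10000 random lists matched on mean signal, whose highest median was 1.58. The 13 are no held-out set, since the whole list was written after the data were seen. Markers of the same cell layer may also vary together, unlike random genes, so this percentile is no independent support. By decile of signal the median difference was -0.02 in the dimmest, 0.50 and 0.39 in deciles 2 and 3 and 0.48 in the brightest. Random lists matched on control signal had a highest median of 2.43, below that of the 13 markers. The marker list was written after the data were seen, so this cannot decide on a general rise of dim probes as the sole cause. With normexp the lists matched on control signal had a median of 1.38 and at most 1.77. The markers then had 2.21, so part of the rise is shared with genes of like signal. Whether such cells would come from dissection or from a change in the animals was not tested, and an effect of LB1 on the liver surface stays open.

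The large number of called probes may in part be technical. The 75th percentile scaling as the sole cause is argued against, since 6041 of 7439 calls were also made in the same direction after quantile normalization. With the array median as reference 4568 were kept and higher calls fell from 4409 to 1658, so the number of calls in each direction rests on the scaling. A stronger 3' bias of the labelled RNA on the LB1 arrays stays open. In 188 genes with a pair of probes of like brightness at most 1000 bases apart, the log2 difference of the probe nearer the 3' end exceeded that of the other by a median of 0.121 (95% bootstrap interval 0.044 to 0.237), and in 59% of genes it was the higher. Over all 960 genes with a pair the median was 0.329 (0.278 to 0.395), with 65.4% positive. How many calls it accounts for was not tested. A biological effect of LB1 stays open and untested. Relative to the spike-ins the median tested probe was 4.66-fold lower on the LB1 arrays, as given above. Whether this lower signal came from RNA amount or quality was not tested, nor how many calls it accounts for.

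Xist, the RNA that coats the inactive X chromosome in females, was low on the array of control replicate 1, although all 4 mice are labelled female. At 3 of its 4 probes the value was 17.2-fold, 23.2-fold and 17.5-fold lower than on control replicate 2. At the antisense transcript Tsix it was 8.51-fold lower, which is not exact, since that probe was not well above background on control replicate 1. Failed spots are argued against by the 4 separate probes. Of the Y-linked probes, 0 of 7 were well above background on that array or on any other. That argues against a male animal only if these probes detect Y-linked RNA, which no male sample here shows. The highest of these 7, a Uty probe, had a signal of 12.6 there against 2.9 on control replicate 2. On LB1 replicates 1 and 2 it had 3.4 and 2.28. The test written beforehand was on genes that escape X inactivation. Kdm6a (-0.90), Eif2s3x (-0.83), Kdm5c (-0.36) and Ddx3x (-0.14) had a median of -0.60 for control replicate 1 minus control replicate 2, which 0.02% of random lists matched on signal reached, while the median of 677 X-linked probes was -0.02 and that of autosomal probes -0.02. Jpx, the fifth gene named, had no probe by that name and gave no value. With a single X chromosome these genes should also be lower than on the LB1 arrays, a comparison added later. That depended on the probe. With the brightest probe of each gene the median difference from the LB1 mean was 0.01 for control replicate 1 and 0.54 for control replicate 2. Kdm6a, Eif2s3x and Ddx3x then lay near the LB1 level on control replicate 1 (differences of -0.02, 0.06 and 0.05), which high values on control replicate 2 would also give, while Kdm5c was 1.50 lower on control replicate 1 and 1.14 lower on control replicate 2. Over all 9 probes well above background on every array, the median was -0.45 for control replicate 1 (-1.75 to 0.58) and 0.19 for control replicate 2. The LB1 arrays differ in group as well, so a single X chromosome stays open. A mislabelled or pooled sample was not tested, and either would bear on every control value given here. No biological explanation tied to the groups was tested for it.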
